A study of Mus musculus with 4 samples.

How the data were processed

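Chromatin immunoprecipitation with an antibody against H3K4me3 was followed by sequencing in left cerebral cortex of female B6CASTF1/J mice aged 2 months. Per the labels, the 4 libraries were 2 technical replicates each of pool J (biological replicate 1) and pool I (biological replicate 2), each pool made of 4 biosamples, with a fragment size range of 200 to 600 bases. Samples were grouped by the pool named in the labels. All 4 libraries carried the same donor record, and the labels do not say whether the biosamples of the pools came from separate animals, so the spread between pools may be technical in part.

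The authors deposited 4 lists of peaks on the mm10 build, per the labels and the text files supplied with each library. Lists termed pseudoreplicated were called on 1 pool alone (pool J, pool I) or on the pooled reads of both, and the replicated list on both pools, per those text files deposited with the libraries. Both libraries of a pool pointed to 1 shared alignment. The aligner, the peak caller and its settings are not given in the sources used here, and neither are the read numbers, so the depth behind each list is unknown. Peak positions are in bases, as deposited, and are given here counted from 1. The deposited display score, at most 1000, was not used. The authors' enrichment value of each peak is a ratio, taken here as fold over a control since the deposited text files list fold-over-control tracks and the labels name a possible control experiment. It is the authors' value for the peak and served only to describe, rank or filter peaks within a list. The deposited −log10 p and −log10 q values were used as filters in alternatives. Of the 25446 replicated peaks, 361 had a q above 0.05, and 71.4% had a −log10 q of at least 10.

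Gene models were those of GENCODE release M21 on the mm10 sequence, with 21938 protein-coding genes. A protein-coding promoter was called marked when a peak overlapped, by at least 1 base, a window of 1000 bases either side of any of the gene's annotated transcript starts. Overlapping peaks and peaks up to 1000 bases apart were merged into domains, a gene took its widest domain, and the widest 5% of the domains of marked genes were called broad. Peaks were assigned in order to windows around the 132721 annotated starts, exons, introns and intergenic sequence, and those outside the windows were called distal. GC content and the observed-to-expected CpG ratio were computed from the sequence of 1 window per gene, that of its 5′-most start. That start need not be the one that carried the peak. Overlap between lists required at least 1 base, and 100 shuffles of positions within chromosomes gave the level by chance. The share of a list had a 95% Wilson interval.

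The lists compared comprised pan-neuronal, excitatory, inhibitory, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural, fibroblast and meningeal, choroid plexus and ependymal, striatal, and diencephalon, midbrain and hindbrain markers. Further lists were of blood, activity-regulated, synaptic, circadian, housekeeping, other tissue, germline and pluripotency, imprinted, X inactivation and escape, and Y-linked genes, and of Hox, olfactory receptor, vomeronasal receptor, clustered protocadherin, ribosomal protein, oxidative phosphorylation, replication-dependent histone, Zfp and keratin families, 32 in all. These lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those stated as added. Each list's marked share was compared with that of the other protein-coding genes by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 32 lists and a threshold of 0.05. Its share of broad domains was compared among marked genes in the same way, over the 31 lists with a marked member. Median width was placed among 10000 random lists of as many marked genes, also matched on deciles of the enrichment value, and positions under percentile 2.5 or above 97.5 are given as low or high with no p-value. Genes were the units of these tests, which describe the lists of peaks and not the variation between animals. With 1 list per pool, values per pool are given as mean ± SD over 2 pools and no p-value was computed between pools.

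The genes named were the 10 widest promoter domains and the 10 of highest enrichment, with 1 gene per domain, that of the start nearest the highest peak. To these were added the first 3 members of each list or the 3 widest of a family, the members that went against their list's majority (or 3 of them where they were more than 5), 5 distal peaks of highest enrichment, the 5 widest distal domains, and the 5 strongest promoters marked in 1 pool alone. Some genes that this rule takes are not reported here. Further members of the lists, Syap1, the 4 escape genes as the highest of the X, and the search for peaks of the other pool near promoters marked in 1 pool alone were chosen after their values were seen.

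Alternatives kept only peaks with a −log10 q of at least 5 or 10, used each single-pool list in place of the replicated one, changed the window to 500 or 2500 bases or to the 5′-most start of each gene, merged peaks not at all or within 3000 bases, took the widest 10%, and required a reciprocal overlap of 50% or the same number of top peaks. Added after the data were seen were a background without receptor and Y-linked genes, random lists matched on the number of starts and on CpG ratio, and matching on enrichment in 100 bins in place of 10. Added too was a comparison of the excitatory list with random lists in each matched property, and a match was read for it only where it changed the position of another list. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

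The steps were tested on simulated data. Overlaps of 694 simulated peaks equalled a count base by base in 100% of cases, and 500 planted promoter domains were recovered with their width in 100%. Among 50 simulations with promoters marked at random, 3 had any list called. With the members of 1 list at a time marked at 98% and the other genes at random, the excitatory list of 14 was called in 0 of 50 simulations, the synaptic list of 19 in 35 and the ribosomal protein list of 83 in 50. With no other list altered, even 14 of 14 marked could hardly pass the adjustment. In the data 14 of 14 had an unadjusted p of 0.00353 (Fisher's exact test). It passed at an adjusted p of 0.00707 because other lists had smaller p-values. With members marked at 15%, the germline list was called in 33 of 50 and the Hox list in 50. Of 200 random lists of 14 marked genes, 15 fell outside percentiles 2.5 to 97.5, and of 200 such lists widened 2-fold, 195 lay above percentile 97.5.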

Results

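Trimethylation of lysine 4 on histone H3 (H3K4me3), a histone mark found at active and poised gene promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the left cerebral cortex of adult female mice. The animals were B6CASTF1/J, the first-generation hybrids of the C57BL/6J and CAST/EiJ inbred strains, and were 2 months old. The series held 4 libraries, prepared as 2 technical replicates from each of 2 pools. Each pool combined 4 cortex biosamples. Pool J carried biological replicate number 1 and pool I number 2. The labels named no treatment, so the design allowed a comparison of the 2 pools and of genes, gene groups and chromosomes within the peak lists. Both libraries of a pool entered 1 peak list, so the spread between technical replicates could not be measured, and the number of reads behind each list was unknown. Peaks were deposited as 4 lists, 1 for pool J, 1 for pool I, 1 for the pooled reads of both, and 1 termed replicated, called on both pools. The replicated list held 25446 peaks with a median width of 1199 bases, of which 4453 met no peak of the pool J list and 2363 none of the pool I list. It covered 37.5 Mb, or 1.42% of the mm10 genome.

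Both pools marked largely the same promoters. Of the 21938 protein-coding genes, 13961 had a promoter peak in both pools, 66 in pool J only and 261 in pool I only. Another 103 had one in the replicated list but in neither pool list. Domain widths of single neuronal genes were close between the pools at some loci and far apart at others. Grin2b, which encodes an NMDA receptor subunit, had a promoter domain of 9865 bases in pool J and 9870 in pool I. Rorb, a nuclear receptor gene of layer IV neurons, had 3955 and 7708, and Bsn, which encodes a presynaptic scaffold, 3884 and 7309. A wider gap lay at Drd1, the dopamine D1 receptor gene, with 1350 bases in pool J and 6862 in pool I.

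Pool J had 21573 peaks and pool I 24508, a mean of 23040.5 ± 2075 (SD, n = 2 pools). Among peaks with a −log10 q of at least 10 the ratio of pool I to pool J was 1.07, against 1.14 among all peaks. With a minimum overlap of 1 base, 96.8% of pool J peaks met a pool I peak (95% Wilson interval 96.5 to 97.0) and 84.0% of pool I peaks met a pool J peak (83.5 to 84.4). Shuffled positions within chromosomes gave 2.90% and 2.61%. These intervals cover counting error only. The 3928 pool I peaks without a partner had a median width of 414 bases and a median rank at percentile 11.2 of the pool I enrichment values, and none of them lay above the median rank. Across genes marked in both pools, Spearman's rho was 0.949 for domain width and 0.871 for enrichment, where genes are not independent replicates. Domains were a median 1.07 times wider in pool I, and 95.2% of them differed by less than 1.5-fold. With 1 list per pool, no p-value was possible for a difference between the pools.

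**Figure D1:**
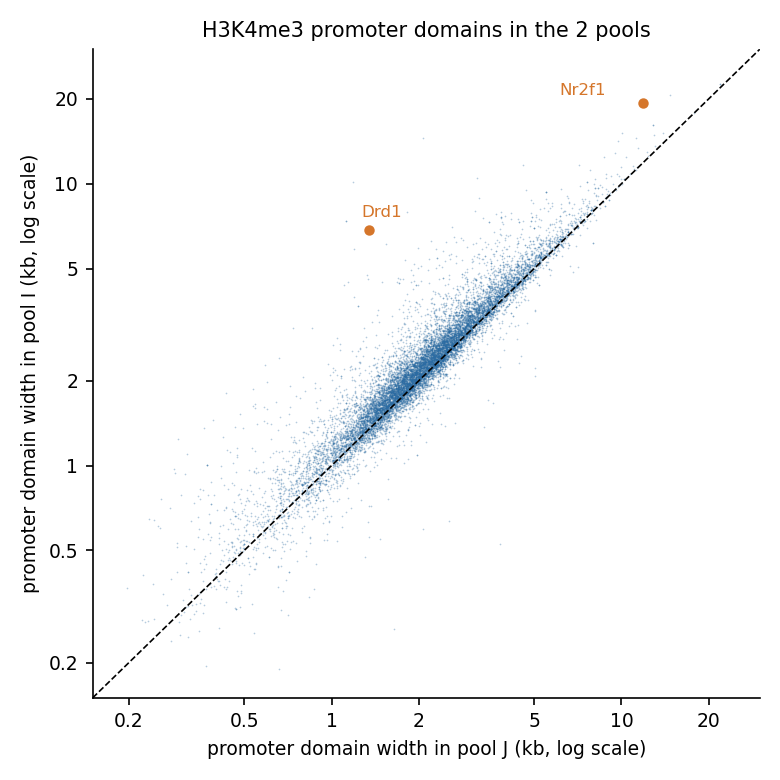
Width of the H3K4me3 promoter domain of each protein-coding gene marked in both pools (1 point per gene), in pool J (horizontal axis, kb, log scale) against pool I (vertical axis, kb, log scale), with a dashed line of equal width. Points follow the line with a Spearman rho of 0.949 across genes, and Drd1 lies far above it with 1350 bases in pool J and 6862 in pool I.

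The 5 promoters of highest enrichment marked in pool J alone were those of Gckr, Gm20538, Lor, Apoa1 and Srp54b. In pool I alone they were those of Sdhaf1, 1700086D15Rik, Sftpc, Gm28035 and Cby3. At 9 of these 10, the exception being Srp54b, the other pool had a peak that ended just outside the promoter window. Sdhaf1, for example, had an enrichment of 31.3 in pool I, and a pool J peak of 31.1 lay 16 bases from its window. At Gckr, with 24.1 in pool J, a pool I peak of 22.4 lay 38 bases away. Such a neighbouring peak, within 1000 bases of the window, was found for 10 of the 66 promoters marked in pool J alone and for 27 of the 261 in pool I alone. Promoters marked in 1 pool alone had weak peaks, with a median at percentile 1.19 of enrichment in pool J and 1.79 in pool I.

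Most of the mark lay at annotated transcription start sites (TSS). Within 1000 bases of a TSS lay 17464 peaks, 68.6% of the replicated list and 86.6% of its bases, while such windows made up 5.88% of the genome. These peaks had a median width of 1683.5 bases and a median enrichment of 17.5. Introns held 3584 peaks, intergenic sequence 3270 and exons 1128, and these 7982 distal peaks had a median width of 496 bases and a median enrichment of 3.87. The share in TSS windows was 83.4% among peaks with a −log10 q of at least 10, which left 3013 distal peaks.

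Promoters rich in CpG dinucleotides carried the mark far more often than CpG-poor ones. The 14293 marked protein-coding promoters were 65.2% of the total. At the 5′-most start of the gene their median observed-to-expected CpG ratio was 0.605, against 0.168 for the 7645 unmarked promoters. From the lowest to the highest decile of that ratio, the marked share went from 3.83% to 98.7%. Median domain width lay between 1571.5 and 1687 bases in deciles 1 to 3, was lowest at 1481 in decile 4 and highest at 2830 in decile 10. The median promoter domain, with peaks up to 1000 bases apart merged, spanned 2124 bases (quartiles 1537 and 2966), and the widest 5%, 715 genes, exceeded 5166 bases. Domains lay mainly downstream of the start site. Among 461 of the widest domains with a single gene, 95.4% extended further downstream than upstream, with medians of 5132 and 1059 bases. The share was similar among 9021 other promoter domains, at 93.1%, with medians of 1361 bases downstream and 549 upstream.

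Several transcription factor genes had very wide promoter domains. Among the 10 widest were Pou3f3 at chromosome 1:42684144-42704528 (20385 bases), Bcl11a at 11:24073453-24092924 (19472) and Nr2f1 at 13:78192693-78211246 (18554). Zeb2 (15136 bases), Nfib (14210), the semaphorin gene Sema7a (13519), Mef2c (13453) and Myt1l (13437) were also among them. The pools varied in some of these. Myt1l had a mean of 13298 ± 366.3 bases (SD, n = 2 pools), Nr2f1 15605.5 ± 5315 (11847 in pool J and 19364 in pool I), Pou3f3 17639.5 ± 4200 and Bcl11a 14518.5 ± 2333 (12869 in pool J and 16168 in pool I).

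The most enriched promoters were a different set. Mdm2, which encodes the ubiquitin ligase of p53, had the highest enrichment at 38.7 with a domain of 2802 bases. Strn4 followed at 38.7, then Hsp90ab1 at 38.6, Cd81 at 38.6, Bcl2l1 at 38.3, Lrch4 at 38.2, Srsf6 at 37.5, Calr at 37.4 and Pias1 at 37.4. No gene was both among the 10 widest and among the 10 most enriched. The domain of Bcl2l1 (6028 bases) also lay among the widest 5%. That of Strn4 did so in the replicated list with 8303 bases, but in neither single-pool list, with 3549 in pool J and 4973 in pool I.

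Some lists of neuronal genes were marked in full. Promoters of each of the 14 pan-neuronal genes (such as Rbfox3, Snap25 and Syt1), the 14 excitatory neuron genes (Slc17a7, Camk2a, Neurod6), the 19 synaptic genes (Dlg4, Shank1, Shank2) and the 15 activity-regulated genes (Fos, Fosb, Arc) carried a replicated peak, in pool J and in pool I as well. So did the 12 circadian genes (Clock, Arntl, Per1) and the 15 housekeeping genes (Actb, Gapdh, Pgk1). Against the other protein-coding genes, marked at 65.1%, each of these 6 lists was above by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 32 lists. The tests of marked share took no account of CpG ratio. The excitatory list's median ratio of 0.441 fell in decile 5 of all promoters, where 81.6% were marked. Adjusted p was 0.00115 for the synaptic list, 0.00473 for the activity-regulated and housekeeping lists, 0.00707 for the pan-neuronal and excitatory lists and 0.0200 for the circadian list.

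Among markers of the other neuron class and of glia and vessels the marked share varied with the setting. Of the inhibitory neuron genes 13 of 14 were marked, Gad1 with an enrichment of 6.91 and Gad2 with 6.10, and the exception was the neuropeptide gene Vip. Astrocyte genes were marked in 12 of 13 cases, with 20.0 at the glutamate transporter gene Slc1a2, and the exception was Gfap. Endothelial genes were marked in 12 of 13 cases, with 5.65 at the tight junction gene Cldn5, and the exception was Ly6c1, which had a peak in pool I only. Adjusted p was 0.0649 for the inhibitory list and 0.0647 for the other 2, short of the threshold of 0.05, while it was 0.0398 and 0.0110 for inhibitory and endothelial genes in the pool I list alone and 0.142 and 0.205 in the pool J list alone (Fisher's exact test). The inhibitory list also passed with windows of 500 bases (adjusted p = 0.0437) and the astrocyte list with windows of 2500 bases (0.0116, Fisher's exact test), while at a −log10 q of at least 10 the endothelial list differed from other genes by −0.81 percentage points. For oligodendrocytes 9 of 11 genes were marked, and Opalin was among those unmarked (adjusted p = 0.430, Fisher's exact test), and for their precursors 7 of 9, without Gpr17 and Neu4 (adjusted p = 0.604, Fisher's exact test). The oligodendrocyte list differed from other genes by 16.7 percentage points, but by −18.5 at a −log10 q of at least 5 and −16.9 at 10. Mbp, the myelin basic protein gene, reached an enrichment of 20.7 at its 5′-most start, in the peak at 18:82474619-82476455. Its widest domain lay at another start, 18:82554617-82558304. Mog had an enrichment of 3.34.

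Microglial genes had few and weak peaks. Of 14 genes 8 had a replicated peak, but 2 had one in pool J and 5 in pool I, and adjusted p was 0.617 by Fisher's exact test. Cx3cr1, the fractalkine receptor gene, had a peak of 211 bases and an enrichment of 3.13, and Tmem119 one of 198 bases and 3.13; neither was in a single-pool list. P2ry12, C1qa and C1qc had no replicated peak. The widest domain of the list was that of Sall1 at 7759 bases. With peaks restricted to a −log10 q of at least 5, the list's marked share differed from that of other genes by −49.7 percentage points (adjusted p = 0.000513, Fisher's exact test). It was −49.7 points in the pool J list alone (adjusted p = 0.000568) and −29.1 in the pool I list alone (adjusted p = 0.0626, Fisher's exact test).

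Mural cell genes were marked in 5 of 9 cases, with an enrichment of 6.37 at Pdgfrb, and fibroblast and meningeal genes in 5 of 9, with 6.30 at Col1a1, both at an adjusted p of 0.728 (Fisher's exact test). Among choroid plexus and ependymal genes 3 of 9 were marked, Foxj1, Kl and Clic6, and Ttr, the most abundant transcript of choroid plexus, was not (adjusted p = 0.102, Fisher's exact test). All 9 striatal genes were marked (adjusted p = 0.0539, Fisher's exact test), but 7 in the pool J list and 6 in the pool I list, with Drd2 and Tac1 in neither and Isl1 in pool J alone. The difference from other genes was 34.9 percentage points in the replicated list, 13.8 in pool J and 1.84 in pool I, and the list passed with the 5′-most start alone (adjusted p = 0.0277, Fisher's exact test). Markers of diencephalon, midbrain and hindbrain were marked in 8 of 14 cases (adjusted p = 0.617, Fisher's exact test), without Irx1, Irx2 and Nkx2-1 among others. Of the 9 choroid plexus, 9 striatal and 14 other regional markers, 1 of 32 was marked in 1 pool alone.

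**Figure D2:**
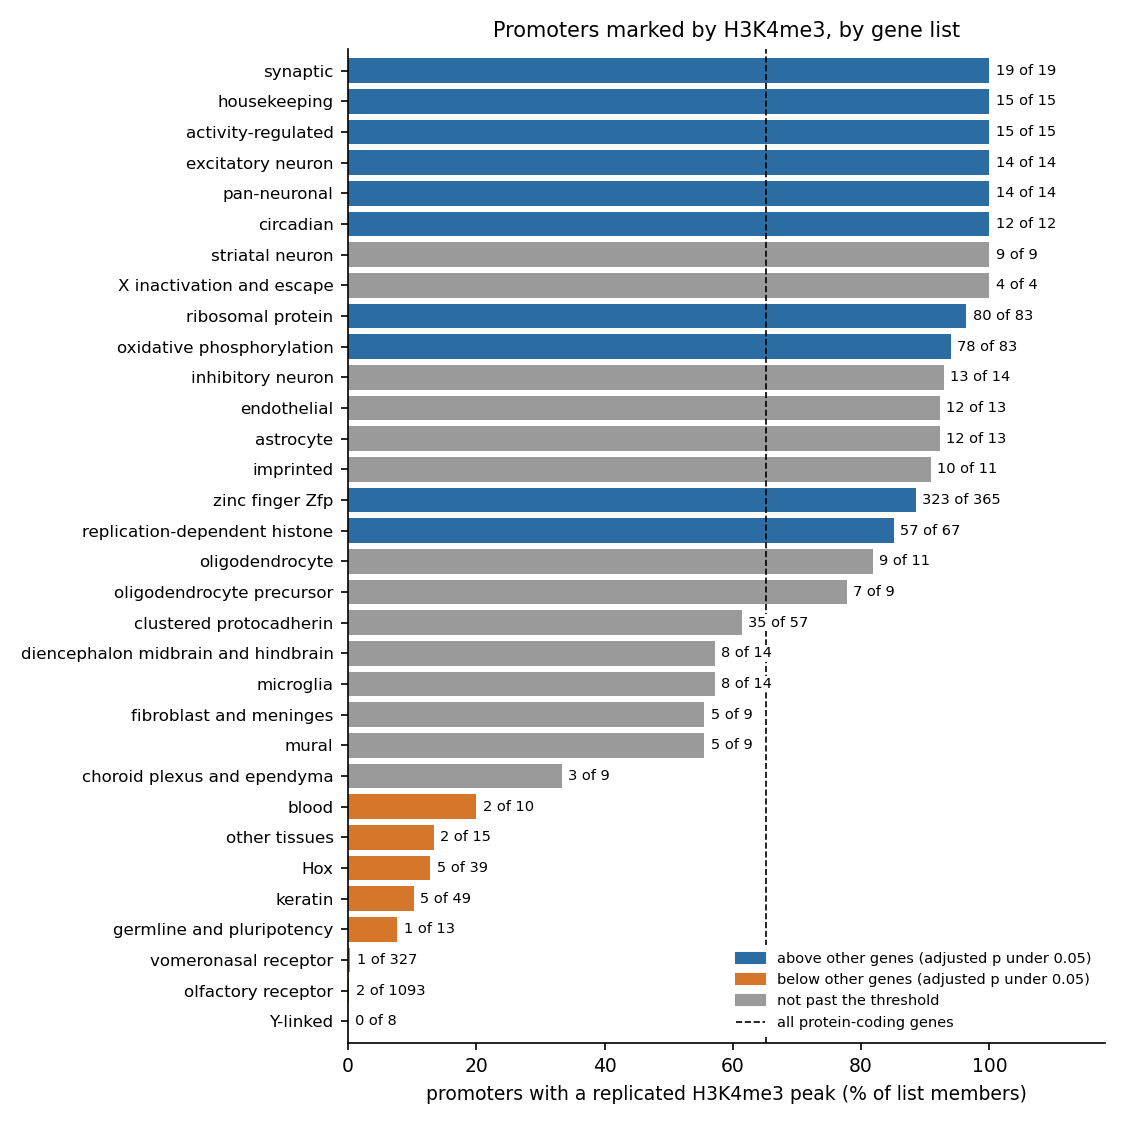
Share of protein-coding list members whose promoter had a replicated H3K4me3 peak (horizontal axis, %), for 32 gene lists, with counts beside the bars and a dashed line at 65.2% for all protein-coding genes. Blue and orange bars were above (10 lists) or below (8 lists) other genes by two-sided Fisher's exact test, and grey bars were not past the threshold.

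Genes of other tissues and lineages were largely unmarked. Marked were 2 of 10 blood genes, Klf1 among them (adjusted p = 0.00878, Fisher's exact test), and 2 of 15 genes of other tissues, Apoa1 and Ckm (adjusted p = 0.000190, Fisher's exact test), where the Ckm domain also covered a start site of Klc3. Of 13 germline and pluripotency genes Dazl alone was marked (adjusted p = 0.000113, Fisher's exact test). Hox genes, which pattern the trunk and hindbrain, were marked in 5 of 39 cases, with 12.1 at Hoxa7 and 8.34 at Hoxd1 (adjusted p = 1.02e-10, Fisher's exact test). Keratin genes were marked in 5 of 49 cases, Krt10 at 19.4 and Krt222 at 18.1 (adjusted p = 1.27e-14, Fisher's exact test). The 1093 olfactory receptor genes had 2 marked members, Olfr94 and Olfr1033, and the 327 vomeronasal receptor genes had 1, Vmn1r4, whose domain also covered a start site of Nt5c3 (adjusted p = 1.96e-148, Fisher's exact test). None of the 8 Y-linked genes was marked (adjusted p = 0.000694, Fisher's exact test), an outcome fixed in advance by the absence of chromosome Y from females.

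Large gene families of basic cell functions were mostly marked. Marked were 80 of 83 ribosomal protein genes, without Rpl3l, Rpl10l and Rpl39l (adjusted p = 5.62e-11, Fisher's exact test), and 78 of 83 genes of oxidative phosphorylation, without Cox6a2, Cox7b2, Cox8b, Cox8c and Atp5o (adjusted p = 3.79e-09, Fisher's exact test). Replication-dependent histone genes were marked in 57 of 67 cases (adjusted p = 0.00115, Fisher's exact test) and Zfp zinc finger genes in 323 of 365 (adjusted p = 1.51e-23, Fisher's exact test). Clustered protocadherins were marked in 35 of 57 cases (adjusted p = 0.617, Fisher's exact test). Of the 57, 19 were marked in pool J and 28 in pool I, and at a −log10 q of at least 10 the list's difference from other genes was −46.7 percentage points (adjusted p = 2.68e-12, Fisher's exact test). In the pool J list alone the difference was −30.7 points and in the pool I list −15.7, with an adjusted p of 1.16e-05 and 0.0279 (Fisher's exact test). Over the 32 lists 10 were above and 8, the Y-linked list among them, below other genes, with 22 at an unadjusted p under 0.05. With olfactory and vomeronasal receptors and Y-linked genes left out of the background, the choroid plexus list was also below (adjusted p = 0.0407, Fisher's exact test).

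Imprinted genes were marked in 10 of 11 protein-coding cases (adjusted p = 0.148, or 0.0326 with windows of 2500 bases, Fisher's exact test), with a domain of 5556 bases at Peg3, and Ndn was the exception. Of the non-coding members Meg3 (4027 bases), Kcnq1ot1 (2945) and Airn (1750) were marked and H19 was not. Among annotated classes of RNA, 91.6% of the 190 bidirectional-promoter lncRNA genes, 35.1% of 2959 antisense genes and 15.1% of 5854 lincRNA genes carried a peak. Processed pseudogenes stood at 1.73% of 9940. Counting only peaks away from protein-coding start sites, the shares were 8.92% for lincRNA genes, 6.69% for antisense genes and 1.19% for processed pseudogenes.

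Excitatory neuron genes had the widest promoter domains of the lists, with a median of 6892 bases over 14 genes. The median of 10000 random lists of as many marked genes was 2124 bases. Mef2c (13453 bases), Tbr1 (13246) and Camk2a (12141, but 5668 in pool J and 8203 in pool I) were among its widest, and Foxp2 (2825) was the narrowest. Synaptic genes followed at 5364 bases, with Grin2b at 9873 and Gria2 at 9494 (6192 in pool J and 9543 in pool I). Activity-regulated genes stood at 5102 bases, with Homer1 at 10439 (7142 in pool J and 11636 in pool I) and Egr3 at 6921. Pan-neuronal genes had a median of 4597.5 bases, circadian genes 4488.5, astrocyte genes 3829, housekeeping genes 2967 and histone genes 2499. These 8 lists lay in the upper 2.5% of the random lists, out of 26 lists with at least 3 marked members. The histone list no longer did when random lists were matched on CpG ratio (percentile 52.8), nor did the housekeeping list when they were matched on the number of starts (97.45), in pool J (90.9), in pool I (96.8), at a −log10 q of at least 10 (91.8) or without merging (96.6). Without merging the histone list lay at percentile 5.58. Per pool, the excitatory median was 6495 ± 953 bases (SD, n = 2 pools) and the synaptic median 5302 ± 909.

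Another 8 lists lay in the lower 2.5%. Their median widths were 291.5 bases for microglia, 358 for Hox genes, 433 for clustered protocadherins, 759 for keratins, 762 for fibroblasts and meninges, 794.5 for diencephalon, midbrain and hindbrain, 1275 for striatum and 1753 for Zfp genes. Several of these medians differed in the single-pool lists. Taking only their members with a peak in pool J and in pool I, medians were 4611.5 and 1300 bases for microglia (2 and 4 genes), 752 and 691.5 for Hox genes, 707 and 561 for protocadherins, 1042 and 1247 for keratins, 1229 and 1172 for the regional markers and 1350 and 1937 for striatum. At a −log10 q of at least 10, striatal, protocadherin and keratin genes no longer lay there (percentiles 22.1, 82.4 and 20.2), and striatal genes lay at percentile 2.89 in pool J and 26.8 in pool I. The microglial and Hox lists could not be placed at that threshold, as fewer than 3 of their members stayed marked. The remaining 10 lay between, with medians of 3719 bases for X-linked escape genes, 3191 for oligodendrocyte precursors, 2692.5 for imprinted genes and 2467.5 for endothelium. Inhibitory neurons had 2325 bases (percentile 71.6, or 98.9 in pool I and 2.48 at a −log10 q of at least 10), oxidative phosphorylation 2243, ribosomal proteins 2216, mural cells 1946, oligodendrocytes 1630 and choroid plexus 1003. The choroid plexus list lay at the bound itself, percentile 2.5. It was low in pool I (1.675), in pool J (2.405) and at a −log10 q of at least 5 (2.085) and 10 (1.4). Matched on decile of enrichment it lay at percentile 45.8. Against random lists matched on decile of enrichment, 11 lists were above and 4 below. The 4 were those of microglia, Hox, protocadherin and Zfp genes. Inhibitory neuron, oligodendrocyte precursor, endothelial and imprinted genes then lay in the upper 2.5%, and housekeeping genes did not (percentile 96.2).

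**Figure D3:**
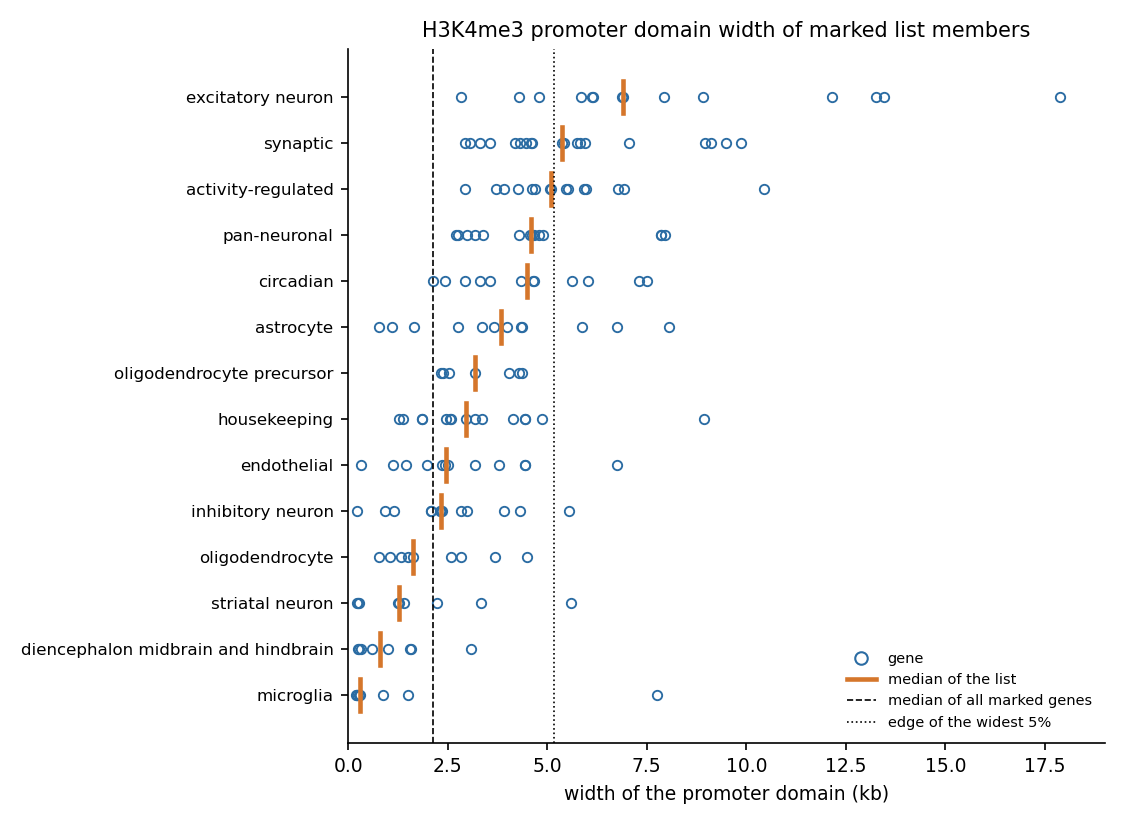
Width of the H3K4me3 promoter domain (horizontal axis, kb) of each marked protein-coding member of 14 gene lists (circles), with the median of each list (orange bars), the median of all marked genes at 2124 bases (dashed line) and the edge of the widest 5% at 5166 bases (dotted line). The excitatory neuron median of 6892 bases lies beyond that edge, and 5 of the 8 marked microglial genes lie at or under 300.0 bases.

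Excitatory, synaptic and activity-regulated genes were concentrated among the widest 5% of domains. Of 14 marked excitatory genes 11 belonged to it, against 4.93% of other marked genes, a difference of 73.6 percentage points (adjusted p = 4.48e-11, two-sided Fisher's exact test, adjusted over 31 lists). Synaptic genes had 10 of 19 (adjusted p = 8.76e-08, Fisher's exact test) and activity-regulated genes 7 of 15 (adjusted p = 3.56e-05, Fisher's exact test), Fos and Npas4 among them. Circadian genes had 4 of 12, Per1, Cry2, Nr1d1 and Dbp, and histone genes 9 of 57, both at an adjusted p of 0.0138 (Fisher's exact test). The 9 histone genes lay in 3 domains, 5 of them in 1 domain of 6269 bases, so they were not independent. Inhibitory neuron genes had 1 of 13 (adjusted p = 0.944, Fisher's exact test), striatal genes 1 of 9 (adjusted p = 0.882, Fisher's exact test), pan-neuronal genes 3 of 14 (adjusted p = 0.129, Fisher's exact test) and astrocyte genes 3 of 12 (adjusted p = 0.101, Fisher's exact test). No list was below, with 9 of 31 at an unadjusted p under 0.05 in either direction by Fisher's exact test. Without merging of neighbouring peaks the excitatory difference was 30.7 points (adjusted p = 0.00328, Fisher's exact test), and merging within 3000 bases gave 21.7 points for activity-regulated genes, against 41.7. The circadian call ended without merging (adjusted p = 0.101), without pool J (0.0867) and at a −log10 q of at least 5 (0.101) and 10 (0.0875), the histone call without merging (0.765) and with the widest 10% (0.425, Fisher's exact test). The pan-neuronal list was above without merging (37.9 points, adjusted p = 0.000506), with merging within 3000 bases (0.0258), with the widest 10% (54.3 points, 9.65e-06), without pool J (0.0258) and without pool I (0.0215), as was the astrocyte list with the widest 10% (0.0168), where the Zfp and ribosomal protein lists were below (0.000384 and 0.0168, Fisher's exact test).

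Chromosome X had lower enrichment than each autosome. The median enrichment of marked promoters was 13.7 on X and 21.1 on the autosomes, a ratio of 0.648, and single autosomes ranged from 20.3 to 21.9. Of 948 X-linked protein-coding promoters 472 were marked, 49.8%, against 66.4% on the autosomes, of which chromosomes 7 and 14 were near X at 53.5% and 54.4%. In the pool J list the medians were 13.2 and 20.8, and in the pool I list 14.1 and 21.1. The synaptic vesicle genes Syn1 and Syp had 15.3 and 11.001, and the housekeeping genes Hprt and Pgk1 had 12.7 and 15.5. Of all 472 marked X promoters the highest were Eif2s3x at 32.4, Kdm6a at 32.03, Kdm5c at 30.2 and Ddx3x at 29.8. These 4 are the protein-coding members of the list of genes known to escape X inactivation, fixed before the data were examined, and the next promoter, that of Syap1, had 23.6. The list's marked share was 4 of 4 (adjusted p = 0.391, Fisher's exact test). Xist, the non-coding RNA expressed from the inactive X, had an enrichment of 18.3, Jpx 20.9, Ftx 20.1 and Tsix 8.77. On chromosome Y, absent from females, 1 replicated peak was listed, Y:90744322-90744830.

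**Figure D4:**
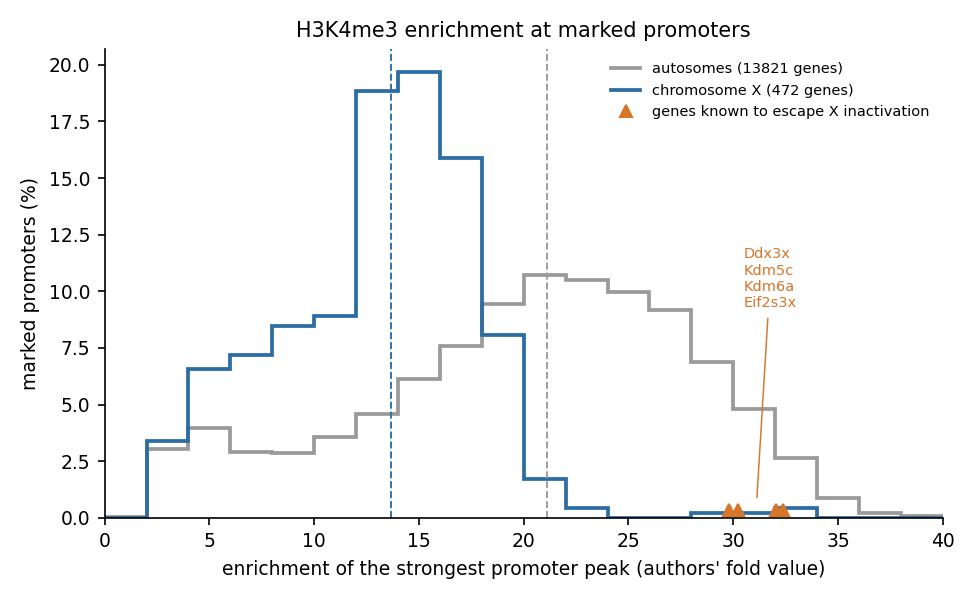
Distribution of the authors' enrichment value at marked protein-coding promoters (horizontal axis, fold; vertical axis, % of marked promoters) for 13821 autosomal and 472 X-linked genes in bins of 2, with dashed lines at the medians of 21.1 and 13.7. Triangles mark the 4 listed escape genes, which lie between 29.8 and 32.4, above every other X-linked promoter.

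Distal peaks included regions as strong as promoters. The most enriched lay at chromosome 13:21709810-21711744, intergenic and 5827 bases from the start site of Hist1h2bl (enrichment 29.7). Next came 17:21531458-21533299 in an intron of 9330136K24Rik near Zfp52 (29.1), 7:98814378-98817106, intergenic, 19219 bases from Wnt11 (27.8), 4:46304335-46305901 in an intron of Gm12446, 38537 bases from Foxe1 (27.7), and 5:104570830-104572596, intergenic, 63446 bases from BC005561 (27.7). The widest distal domain spanned 20816 bases at 15:85665129-85685944, over exons of the non-coding genes Gm49539 and Lncppara and 62984 bases from Ppara. Parts of the promoter-proximal regions of Bcl11a (8665 bases), Pou3f3 (7452) and Sema7a (7209) were next, with an intergenic domain of 7142 bases at 13:21166694-21173835 near Trim27. Each of these 10 regions overlapped peaks in both single-pool lists. The median distal peak lay 14015 bases from a protein-coding start site, and 30.7% lay within 5000 bases of one.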

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

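The background without receptor and Y-linked genes and the matching on enrichment in 100 bins were chosen only after the results were seen. No paired analysis was possible because each pool had 1 peak list and no test compared the pools. Marked promoters ranged from 13520 to 14524 over the settings tried, and the ratio of X to autosomal median enrichment from 0.633 to 0.667. Of the list comparisons of marked promoters under alternatives, 237 had the same call and direction, 14 passed the threshold where the reported value had not, and 5 turned direction with neither value past it. These were oligodendrocytes at −18.5 and −16.9 percentage points at a −log10 q of at least 5 and 10, endothelium at −0.81 at 10, mural cells at 1.84 without pool J and fibroblasts at 0.46 with windows of 2500 bases. Of 217 comparisons of broad domains 177 had the same call and direction, 10 newly passed, 5 no longer passed and 25 turned direction. Of the 25, the histone list alone had been past the threshold, and it stood at −3.26 points without merging (adjusted p = 0.765, Fisher's exact test), where by construction unmerged peaks split the histone clusters. The others passed in neither setting. Inhibitory and endothelial genes had no broad domain, at −5.005 and −5.0046 points at a −log10 q of at least 5, −5.03 at 10, and −5.01 without pool I and without merging. Striatal genes had none without pool I or with merging within 3000 bases (−5.01), and imprinted genes none without merging or with that merging (−5.01) and −0.0189 points with the widest 10%. Merging within 3000 bases and the widest 10% gave 6.11 and 1.09 points for oligodendrocytes and 9.29 and 18.6 for their precursors. Escape genes stood at 19.98 points at a −log10 q of at least 10, 20.001 without pool I, 20.003 without merging and 14.98 with the widest 10%. Protocadherins stood at −2.15 without merging and −4.32 with the widest 10%, and ribosomal proteins at 5.03 with merging within 3000 bases. Median widths of lists moved in 66 of 152 comparisons, and in 21 the position among random lists changed. Domain widths of named genes moved in 174 of 579. Of 88 values for the main results, 64 were the same and 24 moved. Distal peaks numbered 5018 at a −log10 q of at least 5 and 3013 at 10, since these settings keep fewer peaks, and from 5220 to 7271 with 1 pool alone. Peaks in TSS windows made up 76.4% and 83.4% at these thresholds, 75.2% with windows of 2500 bases, and 70.3% to 75.8% with 1 pool alone. The marked share of X promoters was 48.8% and 46.6% at these thresholds and 48.5% to 49.7% with 1 pool alone. Overlap of pool J peaks by pool I was 88.7% with a reciprocal overlap of 50%, 97.46% and 98.3% at a −log10 q of at least 5 and 10, and 93.7% for the same number of top peaks. For pool I peaks by pool J these values were 78.1%, 87.8%, 91.8% and 91.6%. Lists below percentile 2.5 of width numbered 5 at a −log10 q of at least 10, and 4 when matched on enrichment in 10 or in 100 bins. At the threshold of 10 the microglial and Hox lists had too few marked members to be placed. Lists below other genes in broad domains numbered 1 at a −log10 q of at least 10, 1 without merging and 2 with the widest 10%. Except where construction is named, the cause was not tested. With the read depth unknown, a promoter without a peak may hold a mark too weak to be called, as microglial genes were at −49.7 points from other genes at a −log10 q of at least 5.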

Other observations

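Among the tests given here, those of X-linked list members against autosomal members and of microglial genes in finer bins of enrichment were chosen only after the result was seen. The same holds for the matching on the number of transcript starts and on CpG ratio, for the check of how the excitatory list compared with random lists in the matched property, and for the genes picked in the first paragraphs.

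Of the promoters marked in both pools 76.6% had wider domains in pool I, and some single genes had wide gaps. The homeobox genes Dlx2 and Dlx6, which specify forebrain interneurons, had 1200 and 1796 bases in pool J and 3949 and 5365 in pool I. Gad1 and Gad2, the genes of GABA synthesis, had 2688 and 1452 bases in pool J and 5538 and 3573 in pool I. Gaps were also wide at genes of other classes, with 4883 and 8727 bases at the excitatory gene Nrgn and 2681 and 6218 at the endothelial gene Flt1. Dlx1 and Lhx6 went the other way, with 2123 and 3271 bases in pool J and 1772 and 2240 in pool I, and so did the oligodendrocyte gene Mobp, with 1645 and 264. These gaps between 2 pools were not tested.

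Within the clustered protocadherins the median domain was 433 bases. The widest was that of Pcdhgc5, with a domain of 6442 bases at chromosome 18:37819514-37825955, followed by Pcdhac2 with 6438 at 18:37143193-37149630, Pcdhgc3 with 3890 at 18:37805778-37809667, Pcdhgc4 with 3055 and Pcdhga12 with 2512. Pcdha1, Pcdha2 and Pcdha3 had no peak. Among regional markers, the window of the hypothalamic neuropeptide gene Agrp held a peak with an enrichment of 30.8, above the 23.3 of Camk2a. A window can take in a peak of a neighbouring gene, and this was not tested for Agrp. Among meningeal markers Foxc1 had a domain of 7877 bases.

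Marker lists differed in promoter domain width in the replicated list, from 6892 bases for excitatory neurons to 291.5 for microglia, whose medians were 4611.5 in pool J (2 of its 8 marked genes) and 1300 in pool I (4 of them). CpG content was measured at the 5′-most start, which need not carry the peak. So measured, it was argued against as the whole cause for the excitatory list. That list had a lower CpG ratio (0.441) than random lists (0.604) and lay at percentile 100 of lists matched on it. Enrichment and the number of starts were likewise argued against for it, as it lay at percentile 100 of lists matched on either and had no more of either than random lists (18.6 against 20.8 and 4.5 against 4.5), but lower enrichment may account for part of the gap to other lists, as matching on it moved the inhibitory list from percentile 71.6 to 99.995. For microglia, matching on deciles gave percentile 0 but failed, with a median enrichment of 5.74 in the random lists against 3.13. Matching in 100 bins gave percentile 0.975, with 3.27 in the random lists and the microglial list at percentile 6.05 of their enrichment. It cannot decide on weak signal, as the microglial enrichment had a median at percentile 1.27 of marked promoters. Most of the 8 genes also had no peak in pool J. No biological explanation was tested, since the labels name no cell types, and cell mixture stays open.

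Pool I had 24508 peaks and pool J 21573. The pool I peaks that no pool J peak overlapped had a median enrichment at percentile 11.2 of the pool I list. Weak peaks near the calling threshold would have such a median, and depth may explain them. Not all lay near the threshold, as 342 of these 3928 peaks had a −log10 q of at least 10. A share of neighbouring tissue in 1 pool was tested with markers of choroid plexus, striatum and other brain regions, of which 1 of 32 was marked in 1 pool alone, against 326 of 21906 other genes (one-sided Fisher's exact p = 0.382). With 32 markers such a share cannot be told apart from none. Animals differing between the pools stay open as well, since no biological difference between the pools was named in the labels.

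Promoters on chromosome X had a median enrichment of 13.7, against 21.1 on the autosomes. CpG content at the 5′-most start was argued against as the whole cause. The X median lay at percentile 0 of random autosomal lists matched on CpG decile, the lowest of which had 18.0. A different make-up of genes on X was also argued against, since 20 X-linked members of 6 lists had a median of 14.2, at percentile 0 of autosomal members of the same lists, whose median was 22.5. An unmarked inactive copy in each cell may account for the difference, since the 4 listed escape genes, which are expressed from both copies, had a median of 31.1, at percentile 100 of random lists of as many X promoters. Their median also lay above the autosomal 21.1, at percentile 94.4 of all marked genes. Promoters strong in themselves could thus have given the same rank among X promoters. The inactive copy stays a hypothesis, as the alleles were not separated here.

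The replicated peak at Y:90744322-90744830, 509 bases wide with an enrichment of 3.41, was in neither single-pool list, and 43.8% of its 36-base stretches had an exact copy outside chromosome Y, most often on chromosome 7.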
